A study of Mus musculus with 6 samples.

How the data were processed

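Genomic DNA of E14 mouse embryonic stem cells was profiled in 6 Pvu-Seal-seq libraries. Per the labels' protocols, DNA for the 5hmC library was digested with PvuRts1I, tagged with azide-glucose by a phage β-glucosyltransferase, ligated to an adapter at the cut ends, sheared, coupled to biotin and captured on streptavidin beads. The captured DNA then received the other adapter, was released by cleaving a disulfide bond and was amplified. How the 5fC libraries were made, and how 5fC was told from 5hmC, is not given in the sources used here. Per the submitters' processing notes, the tools were CASAVA, bcl2fastq, cutadapt and Bowtie and the genome build was mm9, with no versions. How cut ends were assigned to cytosines, how the common sites of a list were defined and which libraries were summed are not given in the sources used here either.

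The authors deposited 2 tables, for 5hmC and 5fC, whose values are whole-number read counts per listed cytosine, not normalized, with the chromosome, position, dinucleotide and strand. Each table has 1 count per site for several libraries together. The labels of the 5hmC libraries of both cultures name the same 5hmC table, so whether the culture at passage 12 contributes to it is unstated. The names of both tables carry the same mark of a first replicate and of common sites, and the 5hmC table was treated as that of the culture at passage 14. The planned comparisons of technical replicates, of the cultures and of regions by a model over separate libraries need counts per library and were not run. The supplied gene table is of another build than mm9, so gene bodies, promoters, gene lists and named genes were not analysed here, nor could CHG and CHH be separated from dinucleotides alone.

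Both tables were read in full. Every listed position was 1 base long, 0 positions were repeated and the least count was 2. The mitochondrial chromosome was set apart from the nuclear comparisons. Counts summed over listed cytosines were 264008048 reads for 5hmC (median 8 per site) and 102305049 for 5fC (median 12). These sums are not the sequencing depth. They leave out reads at unlisted cytosines, and whether a read can count at more than 1 cytosine is not known. Shares over sites have 95% Wilson intervals, which are narrow because of the number of sites and cover counting error only. A site missing from a list is not shown to lack reads, since the listing rule is not known.

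Counts were made of sites per dinucleotide, of CG dyads listed on 1 or both strands, and of cytosines in both lists on the same base and strand. The share of dyads on both strands was set beside the product of the shares of each strand among the dyads of the other mark. The overlap at CG was set beside random placement over the cytosines of all listed dyads. Leaving out unlisted CG dyads raises this level. Counting cytosines of listed dyads that could not be listed, whose number is not known, lowers it, so it is not a bound. The 20 planned circular shifts of a list within chromosomes gave a mean overlap of 0.318% at CG and 0.102% outside CG, but they move sites off cytosines and were not used as a chance level. Because the lists differ in summed reads, 5hmC reads were also thinned at random. They were thinned to 38.7% of reads to match the 5fC reads and to 10.0% to match the 5fC number of sites. Sites with at least 2 reads left were used. This thinning was chosen after the data were seen and treats reads as independent. It gives a list unlike that of 5fC, in which 153442 sites had 2 reads and 333806 had 8, the most frequent number.

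Reads and sites were summed in windows of 100 kb, with 10 kb as an alternative. Windows were named by a rule fixed before the data were examined: the 3 highest and 3 lowest ratios of 5fC to 5hmC reads among windows with at least the median reads of both marks, and the 3 windows with the most sites of each mark. Density per Mb used the last listed base as the chromosome length. For the excess of reads per site on chromosomes 8 and 11, windows of 1 Mb with at least 100 sites were used. They were placed in 20 groups by site density, with limits set on the windows of the other autosomes. Each window was compared with the median of the other autosomes in its group. Windows denser than any on the other autosomes fell in the top group. Distances between non-CG sites and CG dyads were counted from the non-CG cytosine to the cytosine of the dyad on the same strand.

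Alternatives set in advance were at least 5 or at least 10 reads per site, autosomes alone, weighting by reads, overlap by either strand of a CG, CG or non-CG sites alone and 10 kb windows. Thinning and leaving out sites above 1000 reads were added after the data were seen. No p-values are given, since sites, windows and chromosomes are not replicates. The counting functions were tested on simulated data with 200000 dyads and 50000 non-CG sites and passed 5 of 5 checks. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.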

Results

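The series maps 2 oxidised forms of 5-methylcytosine at single bases in E14 cells, an established line of male mouse embryonic stem cells. 5-hydroxymethylcytosine (5hmC) is the first oxidation product made by the TET enzymes, and 5-formylcytosine (5fC) is the next. The assay, Pvu-Seal-seq, cuts DNA a short fixed distance from a modified cytosine with the enzyme PvuRts1I and pulls down tagged fragments, so that the cut end points back to the cytosine. The labels describe 6 libraries: 2 technical replicates of 5hmC and 2 of 5fC from a culture at passage 14, and 2 technical replicates of 5hmC from another culture at passage 12. The values used here are 1 read count per listed cytosine and mark, pooled over libraries, with every listed cytosine holding at least 2 reads. The 5hmC table held 264008048 reads at 20807956 cytosines and that of 5fC held 102305049 reads at 6248342 cytosines. No value therefore has a replicate error, and no test between the marks could be run. The 95% Wilson intervals cover counting error over sites only, since neighbouring sites and reads without molecular identifiers are not independent.

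On the nuclear chromosomes 20807838 cytosines were listed for 5hmC and 6246187 for 5fC. For both marks most listed cytosines lay in CG dinucleotides. CG made up 76.5% of 5hmC sites (interval 76.4 to 76.5%) and 75.2% of 5fC sites (75.1 to 75.2%). With at least 10 reads per site, 9124396 5hmC and 3977660 5fC sites were left. Outside CG, CA was the most frequent dinucleotide, at 48.8% of 5hmC and 43.6% of 5fC non-CG sites. CT followed at 29.9% and 36.2%, and CC at 21.3% and 20.2%.

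The preference for CG grew with the number of reads at a site, and more steeply for 5hmC. Among 5hmC sites the CG share rose from 52.6% at 2 reads to 98.7% above 64 reads. For 5fC the corresponding shares were 69.3% and 91.4%. The marks were therefore 1.31 percentage points apart over all sites, but 11.1 points apart among sites with at least 10 reads, where CG reached 88.6% for 5hmC and 77.5% for 5fC. By reads, CG took 86.8% of the 5hmC total and 79.0% of the 5fC total. The median site had 8 reads for 5hmC and 12 for 5fC, so sites with few reads make up more of the 5hmC list.

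A CG dinucleotide has a cytosine on each strand, and the strand-resolved lists allow the question of whether both are listed. A cytosine that is not listed is not shown to lack the mark, since no control for the sequence preference of the enzyme was used here. For both marks most CG dyads were listed on 1 strand. Of 11398043 dyads with 5hmC, 39.6% were listed on both strands (interval 39.6 to 39.6%), and of 3900942 dyads with 5fC, 20.3% (20.3 to 20.4%). The share on both strands depended strongly on reads. It rose from 0.634% of 5hmC dyads with 2 to 4 reads to 92.0% in the dyads with the most reads, and from 0.0913% to 81.6% of 5fC dyads. With sites of at least 10 reads alone, 23.8% of 5hmC and 15.7% of 5fC dyads were on both strands. After random thinning of the 5hmC reads to the 5fC total, the 5hmC share was 32.6%, and after thinning to the 5fC number of sites 15.4%, with a median of 3 reads per site against 12 for 5fC. At equal reads per dyad the 5hmC share was higher in every class, for example 35.5% against 7.21% at 9 to 16 reads. None of these comparisons equalises the chance of being listed, since the most frequent read number was 3 in the 5hmC list and 8 in the 5fC list and the listing rule is not known.

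A dyad enters a list through either strand, so each mark was also counted among the dyads of the other. Among dyads with 5fC, 51.8% had 5hmC on both strands, against 52.3% if the strands were listed independently of each other. Among dyads with 5hmC, 6.79% had 5fC on both strands, 1.78 times the 3.82% for independent strands. Neither comparison decides whether the strands of a dyad were listed independently, since the marks shared their strand. Of dyads in both lists but not on both strands for either mark, 79.8% had the marks on the same strand. Choosing dyads by a mark therefore favours the other mark on that strand, which can lower its share on both strands. Read numbers on the plus and minus cytosine of a dyad were weakly related, with a Spearman correlation across dyads of 0.17 for 5hmC and 0.11 for 5fC. Dyads are not independent replicates.

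**Figure D1:**
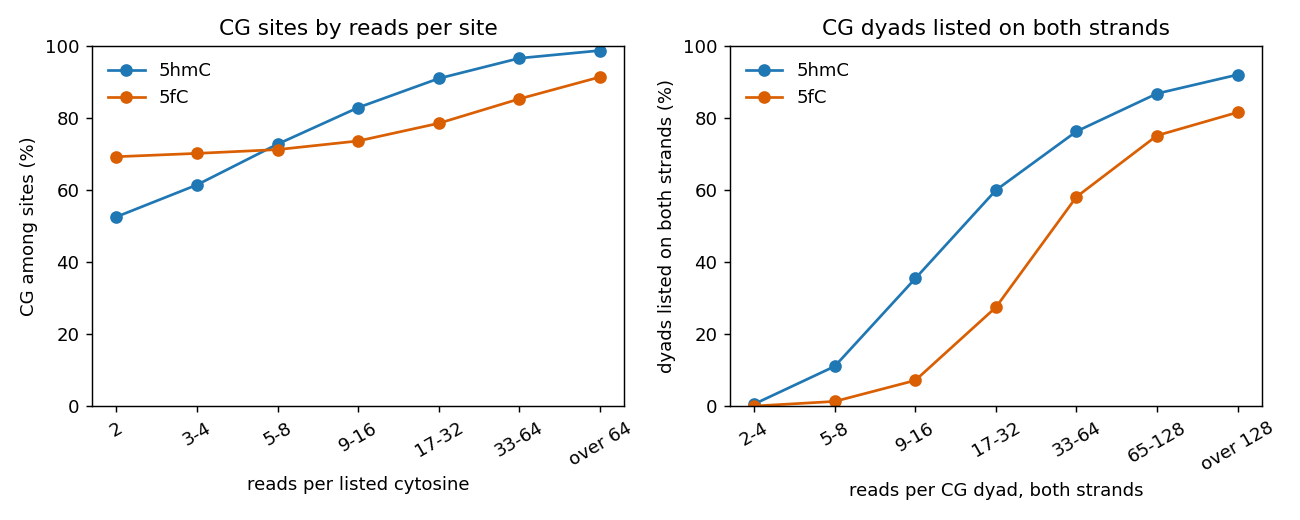
Left, the percentage of listed cytosines in CG context by the number of reads at the cytosine; right, the percentage of CG dyads listed on both strands by the reads of the dyad, for 5hmC (blue) and 5fC (orange). Both shares rise with reads for both marks, up to 98.7% and 91.4% CG and up to 92.0% and 81.6% of dyads on both strands.

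5fC is made from 5hmC, and the lists were compared base by base to ask how often both were found at the same cytosine. Most 5fC sites were also 5hmC sites: 76.3% of all 5fC sites (interval 76.3 to 76.4%) were listed for 5hmC on the same base and strand. The overlap was 83.2% at CG and 55.6% outside CG, and 71.1% and 31.8% with at least 10 reads in both lists. In the other direction, 22.9% of 5hmC sites were listed for 5fC. Counting either strand of the same CG, 92.8% of 5fC dyads had 5hmC and 31.8% of 5hmC dyads had 5fC. How 5fC was told from 5hmC is not given in the sources used here. Carry-over of 5hmC signal into the 5fC list could add to this overlap, to the shared strand and to the window correlations below. It was not tested on the nuclear chromosomes.

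Random placement over the 23357674 cytosines of all listed dyads would give 68.1%, below the 83.2% found at CG. That level takes all of these cytosines as able to be listed, which is not known. If fewer could be listed it would be higher, so overlap by chance is not excluded. No chance level was computed outside CG. Overlap rose with reads, from 70.9% of CG 5fC sites with 2 reads to 99.0% above 64 reads, and from 7.55% to 91.9% of CG 5hmC sites. Shared sites had a median of 17 5hmC reads, against 7 at 5hmC sites without 5fC. The read numbers of the marks at the 4768130 shared sites had a Spearman correlation of 0.34. After thinning 5hmC to the 5fC reads the overlap was 76.6% at CG and 44.2% outside CG.

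The marks also shared their strand. Of 1392417 dyads listed on 1 strand for each mark, 79.8% had both marks on the same strand (interval 79.8 to 79.9%), against 50% for random strands. Where both marks were listed, the log2 ratios of plus to minus reads of 5hmC and 5fC correlated across dyads (Spearman 0.37, Pearson 0.37). Among the 70855 dyads with at least 60 reads for each mark, Spearman was 0.68 and Pearson 0.65. Both marks were read from cuts of the same enzyme, and no control for its sequence preference was used here.

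Along the genome the marks followed each other closely. Over 25520 windows of 100 kb, the numbers of 5hmC and 5fC reads had a Spearman correlation of 0.989, and over windows of 10 kb it was 0.956. Windows are not independent replicates. The ratio of 5fC to 5hmC reads, divided by its genome-wide value of 0.387, ran from 0.716 at the 5th to 1.32 at the 95th percentile of windows with at least the median reads of both marks, a 1.84-fold range that widened to 2.99-fold in 10 kb windows. Of these 12358 windows, 4 lay above 2 times the genome-wide ratio, and the lowest lay at 0.510 times.

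5fC was more concentrated than 5hmC in the densest parts of the genome. The densest 10% of windows held 33.7% of 5fC sites and 25.2% of 5hmC sites. From the windows with the fewest to those with the most 5hmC sites, the number of 5fC sites per 5hmC site rose from 0.118 to 0.394, a 3.33-fold increase. 5hmC thinned to the 5fC number of sites rose 2.00-fold, and thinned to the 5fC reads 1.22-fold. Neither is the rise expected from depth alone, since the thinned lists keep sites from 2 reads upward and the 5fC list has few of them. By reads, without sites above 1000 reads, the ratio of 5fC to 5hmC rose 2.21-fold. These windows covered all nuclear chromosomes, which differed in 5fC sites per 5hmC site. The number was 0.156 on X, 0.357 on chromosome 8, 0.382 on chromosome 11 and 0.473 on Y. On the other 17 autosomes it was between 0.268 and 0.314. The rise was not computed within chromosomes, so differences between chromosomes may be part of it.

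**Figure D2:**
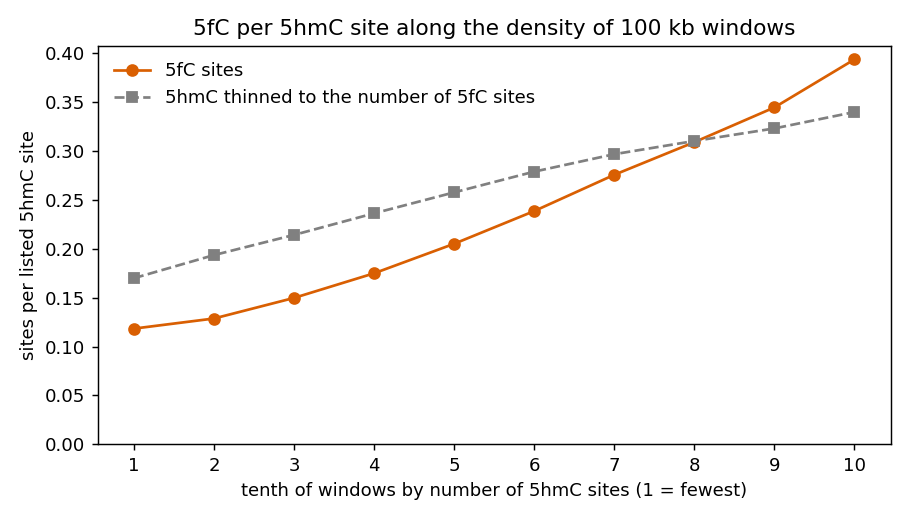
Sites per listed 5hmC site (vertical) over 10 equal groups of 100 kb windows ordered by their number of 5hmC sites (horizontal), for 5fC (orange) and for 5hmC thinned to the number of 5fC sites (grey). 5fC rises from 0.118 to 0.394, and the thinned 5hmC, kept from 2 reads upward, from 0.170 to 0.340.

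Windows named by the rule set in advance are given in mm9 coordinates, and genes in them are not named because no mm9 annotation was used here. The highest 5fC to 5hmC ratio was 3.54 times the genome-wide value, on chromosome 9 from 35100001 to 35200000, with 104982 5fC and 76521 5hmC reads. Next were chromosome 2 from 98500001 to 98600000 at 2.44 times, and chromosome 12 from 3100001 to 3200000 at 2.32 times, the latter close to the centromeric gap of the assembly. The lowest ratios were 0.510 times on chromosome 12 from 108300001 to 108400000, 0.521 on chromosome 14 from 60600001 to 60700000 and 0.527 on chromosome 3 from 136500001 to 136600000. Each of these 3 windows had between 1018 and 1179 5hmC sites but between 166 and 178 5fC sites.

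A few cytosines with very many reads moved the highest ratios in both directions and hardly moved the lowest. Sites above 1000 reads numbered 172 for 5hmC and 169 for 5fC and held 0.621% and 1.33% of reads. Picked after their values were seen, the deepest cytosines of both lists were positions 98503014 and 98507265 on the minus strand of chromosome 2, with 417382 and 340509 5hmC reads and 375023 and 149169 5fC reads. Without sites above 1000 reads the window at 3.54 times on chromosome 9 fell to 2.34 times and that on chromosome 12 to 1.90 times, whereas the chromosome 2 window rose to 4.59 times. The highest ratios were then 5.08 times on chromosome 9 from 3000001 to 3100000, the 4.59 times on chromosome 2 and 3.98 times on chromosome X from 139900001 to 140000000. The 3 lowest windows were the same. Sites were left out of each list by their reads in that list. A cytosine could therefore lose its 5hmC reads and keep its fewer 5fC reads. That alone can raise a ratio, so the rises are not shown to be traits of the windows.

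Chromosome 11 from 117900001 to 118000000 held the most 5hmC sites, 4015, and 2178 5fC sites. Chromosome 8 from 123000001 to 123100000 followed with 3570 and 1871, and chromosome 5 from 116300001 to 116400000 with 3486 and 1395. By 5fC the leading window was chromosome 11 from 3000001 to 3100000, next to the centromeric gap, with 2350 5fC and 3433 5hmC sites. The ratio of 5fC to 5hmC reads in these 4 windows was between 1.18 and 1.43 times the genome-wide value.

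Sites of both marks were denser on chromosomes 8 and 11 than on any other chromosome, and sparse on chromosome X. Chromosome 11 had 1.57 times the genome-wide 5hmC sites per Mb and 2.00 times the 5fC sites. Chromosome 8 had 1.31 and 1.56 times. The other 17 autosomes lay between 0.832 and 1.24 for 5hmC and between 0.769 and 1.29 for 5fC. Chromosome X, present as a single copy in male cells, had 0.281 times the genome-wide 5hmC density and 0.146 times the 5fC density, or 0.182 and 0.123 times by reads.

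Reads per site on these chromosomes also stood above the other autosomes for 5hmC, at 15.2 on chromosome 8 and 15.8 on chromosome 11 against 11.8 to 13.2 on the other autosomes and 8.21 on X. For 5fC the values were 17.8 and 18.1 against 15.5 to 18.4, the upper end being chromosome 2 with the deepest cytosines. Chromosome Y had the highest means, 16.8 for 5hmC and 20.4 for 5fC, but medians of 5 and 12 reads, of which the 5hmC median was the lowest of the nuclear chromosomes. The CG share of 5hmC sites was lower on both, 72.5% on chromosome 8 and 72.0% on chromosome 11, than the 75.4 to 78.6% of the other autosomes. On X it was 87.5%. At most 2 cultures stand behind these values, which describe their DNA and not the line in general.

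**Figure D3:**
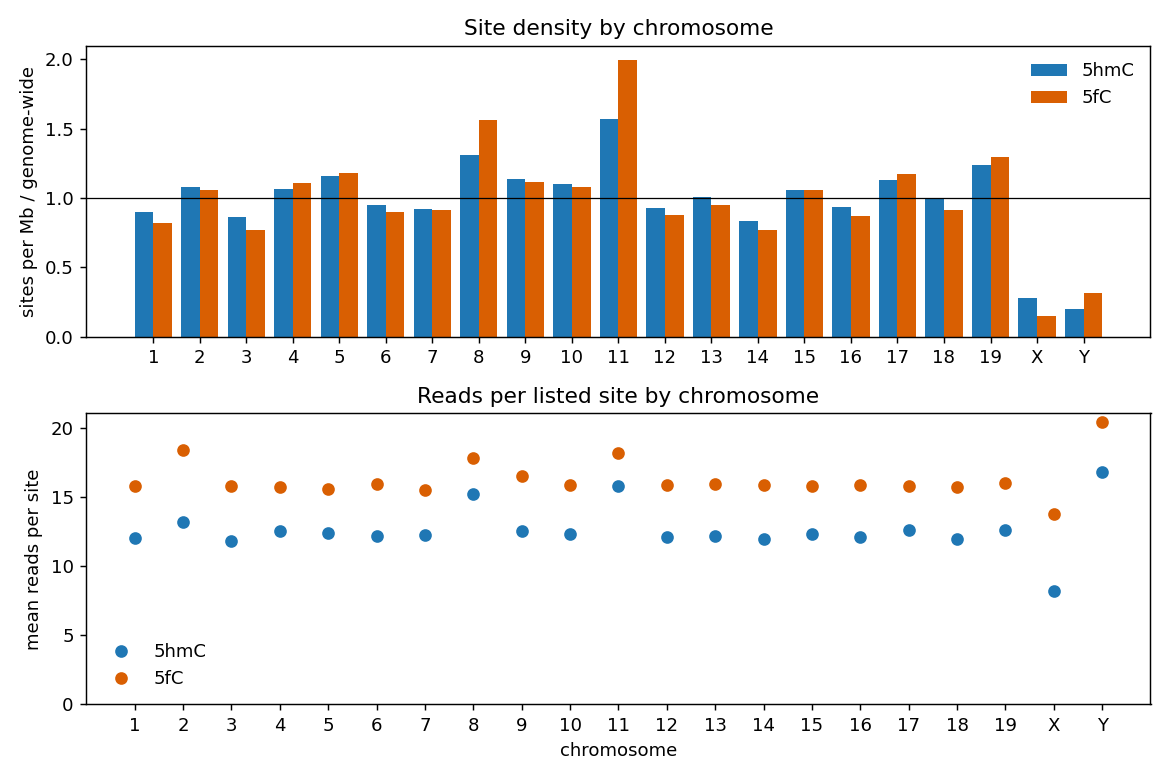
Top, listed sites per Mb divided by the genome-wide value for each nuclear chromosome; bottom, mean reads per listed site, for 5hmC (blue) and 5fC (orange). Chromosomes 8 and 11 stand above the other autosomes in density, at 1.31 and 1.57 for 5hmC and 1.56 and 2.00 for 5fC, and X lies at 0.281 and 0.146.

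Most sites outside CG had a CG site at a fixed distance, and the rest did not. A listed CG dyad lay 20 to 23 bases downstream, along the strand of the non-CG cytosine, for 62.2% of 5hmC non-CG sites (interval 62.2 to 62.3%) and 56.9% of 5fC non-CG sites (56.9 to 57.0%). At the matching distance upstream the shares were 5.95% and 4.43%, and 30 to 33 bases downstream 5.09% and 3.86%. CG sites themselves had a listed CG 20 to 23 bases downstream in 6.70% and 7.32% of cases. For CG sites the shares were 4.71% and 4.30% at the matching distance upstream, and 4.23% and 3.36% at 30 to 33 bases downstream. By dinucleotide the share was 73.1% for CT, 63.3% for CC and 55.1% for CA among 5hmC sites, and between 54.8% and 59.3% for the 3 dinucleotides among 5fC sites. With these non-CG sites left out, CG would make up 89.6% of 5hmC and 87.5% of 5fC sites.

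**Figure D4:**
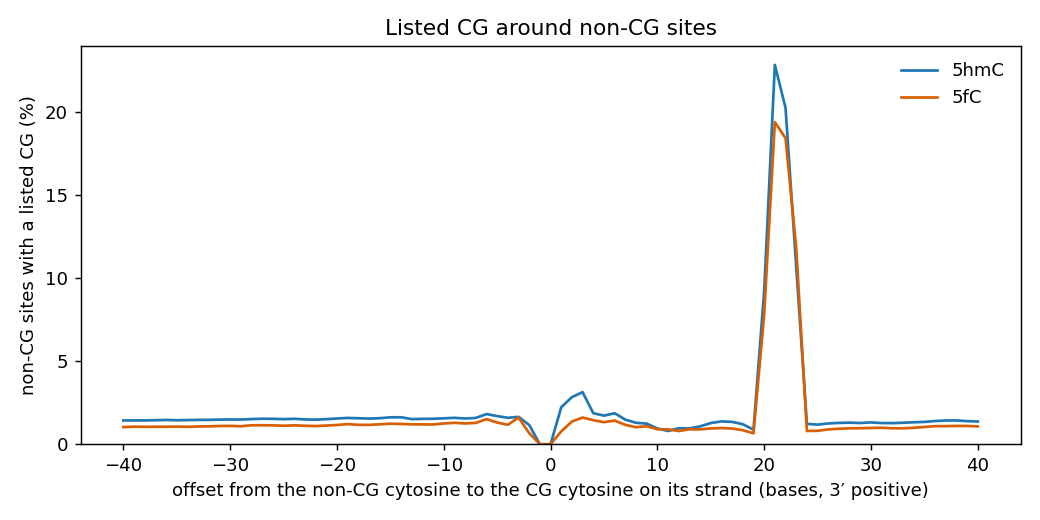
Percentage of non-CG sites with a listed CG dyad at each offset (horizontal, in bases along the strand of the non-CG cytosine, downstream positive), for 5hmC (blue) and 5fC (orange). The peak at 20 to 23 bases downstream reaches 22.8% for 5hmC and 19.4% for 5fC at 21 bases, against 1.23% and 0.798% at 24 bases.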

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

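Of the tests in this part, the comparison of 5fC with 5hmC reads and the CG share of mitochondrial sites were chosen only after the result was seen, and the share of the 10 deepest positions was fixed before it.

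The mitochondrial chromosome lies outside the nuclear comparisons and is listed here because it had more than the 3 reads that a count of 0 allows, a bound that any background passes and that does not tell signal from background. No control library was used here. It held 52769 5fC reads at 2155 sites, 0.0516% of all 5fC reads, and 1144 5hmC reads at 118 sites. Of the 118 5hmC sites, 112 were also 5fC sites. CA and CT made up 37.1% and 36.7% of mitochondrial 5fC sites.

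Carry-over of 5hmC signal as the source of the mitochondrial 5fC reads is argued against by the ratio of 5fC to 5hmC reads. It was 46.1 on the mitochondrial chromosome and 0.387 on the nuclear ones. This does not speak to carry-over at nuclear sites. A few positions taking most reads are argued against by the 10 deepest positions, which held 4.01% of the mitochondrial 5fC reads. Background of the 5fC libraries, such as capture of unmodified DNA from a genome present in many copies, may also give such reads: 11.8% of the mitochondrial 5fC sites were CG (interval 10.5 to 13.3%), against 75.2% in the nucleus, but background and 5fC on mitochondrial DNA cannot be told apart without a library lacking 5fC. No biological explanation was tested, since the samples form no group that would change mitochondrial 5fC.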

How the results depend on the processing

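Of the alternatives, thinning and leaving out sites above 1000 reads were chosen only after the data were seen. No paired analysis was possible because the tables hold 1 pooled read number per site and no value per replicate. For the same reason other size factors, DESeq2, no low-count filter, the replicate block, leaving out each library and the replicate agreement in windows were not run, and promoters of 2 kb and gene lists were not run without an mm9 annotation. Intervals over so many sites are so narrow that nearly any setting moves a share, and correlations and densities have no interval, so small moves are listed too. Directions between the marks held in these settings except for strand pairing after thinning to the 5fC number of sites, which left fewer reads per site than 5fC has, and the causes of the moves were not tested beyond what each setting removes. With at least 10 reads there were 9124396 5hmC and 3977660 5fC sites; with at least 5 reads, autosomes alone or 5hmC thinned to the 5fC reads, the numbers of sites stayed within 1.5 times, and thinning to the 5fC number of sites left 6247186 5hmC sites by construction. The CG share of 5hmC was 82.4% with at least 5 reads, 88.6% with at least 10, 86.8% by reads, again 86.8% by reads without sites above 1000 reads and 80.9% thinned to the 5fC reads; that of 5fC was 75.8%, 77.5%, 79.0% and 79.1% in the first 4 settings, and the difference 6.68, 11.1, 7.87, 7.73 and 5.76 points. Both-strand dyads were 33.4% and 23.8% for 5hmC and 19.103% and 15.68% for 5fC with at least 5 and at least 10 reads, and 32.6% and 15.4% for 5hmC thinned to the 5fC reads and to the 5fC number of sites. The same-strand share was 80.7% and 83.0% with at least 5 and 10 reads. Overlap at CG was 92.8% by either strand, 78.8% and 71.1% with at least 5 and 10 reads in both lists and 76.6% thinned; outside CG it was 46.3%, 31.8% and 44.2%. The share of non-CG sites with a CG 20 to 23 bases downstream was 71.5% and 77.5% for 5hmC and 58.4% and 62.3% for 5fC with at least 5 and 10 reads. By reads, density over the genome was 1.58, 1.95 and 0.182 for 5hmC and 1.70, 2.21 and 0.123 for 5fC on chromosomes 8, 11 and X. The window correlation was 0.988 for CG sites, 0.979 for non-CG sites, 0.956 in 10 kb windows and 0.989 without sites above 1000 reads, and the ratio of the 95th to the 5th percentile, 1.84 in the main setting, was 1.87, 1.79, 2.99 and 1.84. The densest 10% of windows held 29.7% of 5hmC and 36.4% of 5fC reads, 28.4% and 39.9% of sites in 10 kb windows, and 26.0% and 28.8% of 5hmC sites thinned to the 5fC reads and to the 5fC sites. Depth limits which sites are listed, by a rule that is not known, and the shares on both strands and in both lists move with reads.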

Other observations

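Of the tests in this part, the comparison in groups of site density and the share of 1 Mb windows were chosen only after the results were seen. So were the look at how the lists end at low reads and the comparison with the upstream side. The tests without sites above 100 reads, with thinning to 2 of 3 reads and of read correlations were fixed before theirs.

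Non-CG sites without a CG site 20 to 23 bases downstream differed in sequence from those with one. CA made up 58.0% of the 1848547 5hmC non-CG sites without such a CG (interval 57.9 to 58.1%) and 43.2% of the 3048015 with one. Among sites with at least 10 reads the shares were 59.6% and 45.9%. CT was 21.3% without and 35.1% with a CG at that distance. For 5fC the contrast was smaller, with CA at 45.9% of the 668139 sites without and 42.0% of the 883803 with such a CG. CA is the main non-CG target of DNA methylation in embryonic stem cells. The share of CA among all genomic cytosines was not set beside these values, and whether these sites are modified was not tested.

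Chromosome Y, with 2139 5fC and 4522 5hmC sites, differed from the other nuclear chromosomes in its 5fC sites. CG made up 25.1% of them, against 72.5% of the Y 5hmC sites, and 38.1% were also 5hmC sites, against 69.1% on X and 75.7% or more on the autosomes.

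Within groups of windows set by site density, sites on chromosomes 8 and 11 carried more reads than those on the other 17 autosomes. The lowest log2 excess of the 4 combinations of chromosome and mark was 0.139, above the highest of the other autosomes (0.0190). Denser windows are not excluded as a cause by this. The top group took in windows denser than any on the other autosomes, and their number was not counted. A few very deep sites are argued against as the whole cause by an excess of 0.114 without sites above 100 reads. Trisomy of 8 or 11 is a frequent change in cultured mouse embryonic stem cells, but thinning these chromosomes to 2 of 3 reads, as fixed in advance for 3 copies against 2, overshot: the log2 excess of 5hmC became -0.220 on chromosome 8 and -0.204 on chromosome 11, against -0.0234 to 0.0186 on the other autosomes. That prediction failed, but it does not decide on 3 copies against 2 in all cells. Thinning takes reads as independent and the listing rule as a plain cut at 2 reads, and neither is known to hold. Reads per Mb, which need no thinning, were 1.58 and 1.70 times genome-wide on chromosome 8 for 5hmC and 5fC. On chromosome 11 they were 1.95 and 2.21 times. The other 17 autosomes lay between 0.782 and 1.23 for 5hmC and between 0.743 and 1.26 for 5fC. These reads per Mb are not adjusted for site density and do not decide on a number of copies. The thinned 5fC, at -0.408 and -0.387, was not counted because its list has few sites near 2 reads (153442, against 333806 at 8 reads). A smaller scaling, such as a gain in part of the cells, was not tested. A copy gain that adds molecules and not reads per molecule, an explanation added after that failure, may still apply. At least 89.7% of 1 Mb windows lay above the median of the other autosomes in their density group. Many windows of the other autosomes also lie above that median. Copy number and a higher level of the marks cannot be told apart without an input library, and no biological explanation was tested.

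The fixed distance between non-CG and CG sites is not what the density of cytosines and CGs around the site would give, since the share with a CG at the same distance upstream was at most 5.95%. PvuRts1I prefers to cut between a modified cytosine and another cytosine across the cut, so a candidate explanation is that both cytosines of 1 cut were listed for 1 modified CG. That predicted read numbers that correlate more with the CG at this distance than with a CG 30 to 33 bases downstream. The Spearman correlations differed by 0.298 for 5hmC, past the 0.1 set in advance, and by 0.0702 for 5fC, short of it. By that test alone a shared cut and modified non-CG cytosines cannot be told apart for both marks together. The spacing argues against most of the non-CG sites being listed independently of the CG. Such a CG lay downstream of 62.2% and 56.9% of 5hmC and 5fC non-CG sites. Upstream the shares were 5.95% and 4.43%, and downstream of CG sites 6.70% and 7.32%. The latter are not free of the spacing, since upstream of CG sites the shares were lower, at 4.71% and 4.30%. Whether the non-CG cytosine of such a pair is also modified was not tested. No biological explanation was tested.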
